A study of Arabidopsis thaliana with 15 samples.

How the data were processed

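Poly(A) RNA of Arabidopsis thaliana seedlings (accession Col-0) was profiled in 15 libraries that fall into 5 groups of 3. NAD-seq attaches biotin to RNA whose first nucleotide carries NAD+ in place of the usual m7G cap, and captures it on streptavidin. SPAAC is the version with a copper-free click reaction, and CuAAC is the version with a copper-catalysed click reaction. Both were run on RNA treated with an antibody against the m7G cap (m7G-depleted) and on mock-treated RNA, and standard mRNA-seq was run on the mock-treated RNA. A library made without the enzyme that starts the tagging was not analysed here, so a higher level in NAD-seq than in mRNA-seq can include RNA captured without a tag. Per the labels' protocols, RNA was fragmented and primed at random in a directional library kit, and E. coli tRNA was added as carrier before the click reactions.

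The authors deposited raw read counts per gene, a whole-number count for each of 37361 genes in each library, with the summed exon length of the gene, per the file headers. The submitters' processing notes name STAR 2.7.3a, featureCounts 2.0.0 and DESeq2, without saying which step used which. The genome build is not given in the sources used here. Of the gene identifiers, 37065 (99.2%) matched the TAIR10.1 RefSeq annotation, and 99.5% of those had the same summed exon length in the deposited files and in that annotation. Coordinates, symbols and GC content were therefore taken from TAIR10.1. Library totals ran from 3806556 to 19798778 counts.

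The counting did not separate strands. AT2G08665 and its antisense partner AT2G34420 had identical counts in all 15 libraries, and 29 of 1878 opposite-strand pairs with over 1000 counts for each gene were identical in every library. Values of genes that overlap another gene are therefore uncertain. Sharing of reads between near-identical paralogs such as the CAB genes, or between nuclear and organelle genes, was not tested. Values of genes that may share reads are treated as uncertain. Replicates of a group were compared by a chi-square of their counts over genes. The statistic per degree of freedom ran from 4.04 to 16.5, so replicates differed by more than sampling noise.

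Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM factors, filterByExpr) in R 4.3.3, with all 15 libraries in a joint fit by group. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its fold change was at least 2. The filter left 21456 genes, and the common biological coefficient of variation was 12.3%. CPM values are TMM-scaled shares of the library count, given as mean ± SD with n = 3, and fold changes are log2 values ± SE. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 14 lists and 9 comparisons, and again with an estimated correlation. Each p given for a list is adjusted in this way. The labels do not say that the replicates came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical. Read shares were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3 libraries.

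The replicate numbers in the labels pair the samples. The deviations of libraries from their group means correlated above 0.1 in 30 of 30 same-number pairs across groups (0.183 to 0.748, median 0.54, against a median of -0.13 for other pairs, across 10920 genes), and all 15 libraries correlated best with their own number. The fit without a replicate block was chosen before the data were examined, as were the comparisons, the lists and the alternatives, of which the blocked fit was 1. The fits that left out a library had no block and kept the libraries of the same number in other groups. Whether a call that ended in them would hold with the block was not tested.

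The 14 lists covered chloroplast-encoded and mitochondria-encoded genes, photosystem and light-harvesting, carbon fixation, cytosolic ribosomal proteins, antioxidant and redox, cold and dehydration, very large proteins, NAD metabolism and decapping, cytokinin signalling, the circadian clock, jasmonate and defence, reference genes and root markers. In the list build, 2 members were dropped because the reference gives them another symbol. Named genes follow a fixed rule. For each of the first 5 comparisons they are the 4 called genes with the highest and the 4 with the lowest fold change, at a mean CPM of at least 10 and with no overlap between libraries of the compared groups, and the called members of each list with the largest change (up to 2 or 1, by list). List members are taken at a mean CPM of at least 10, and a list with no called member at that level gives its member with the smallest adjusted p. The remaining comparisons take 2 genes in each direction. Other genes are marked where they were chosen after their values were seen.

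The testing code was checked on simulated counts with known changes. These changes were placed only in genes above a minimum expected count, so the shares called do not hold for weak genes. For SPAAC against mRNA, the share called by adjusted p among 20240 simulated genes tested was lowest at a log2 change of -1 (72.73% of 33 genes), 79.41% of 34 genes at a log2 change of 1, 96.97% of 33 genes at each log2 change of -2 and 2, and highest at a log2 change of 1.585 (100% of 34 genes). For SPAAC against CuAAC, among 20590 genes, it was 93.94% of 33 genes at a log2 change of -1, 97.06% of 34 genes at a log2 change of 1 and lowest at 1.585 (88.24% of 34 genes). For depletion in SPAAC, among 20950 genes, it was 90.91% of 33 genes at a log2 change of -1, the lowest, and 97.06% of 34 genes at a log2 change of 1. The unchanged genes called by adjusted p numbered 23, 14 and 14 in these simulations.

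The alternatives were DESeq2 size factors, library totals without composition factors, TMM on nuclear genes, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of 5 CPM in 3 libraries, a fit of the compared groups alone, a replicate block, no fold threshold, glmTreat against a fold of 2, per-library smooth trends in length and GC (mgcv 1.9.3) with and without the block, and leaving out each library. The fits with length and GC offsets tested 21263 genes, since they hold no organelle genes, and the offsets remove a trend with length by construction. The shared and kept genes under all of these but DESeq2 and the left-out libraries, the called list members with offsets or library totals, and RR3 without the reads counted for AT2G09250, which lies in its last exon, were added after the data were examined. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.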

Results

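The study profiled NAD+-capped transcripts of Arabidopsis seedlings with SPAAC and CuAAC NAD-seq, on mock-treated and m7G-depleted RNA, beside mRNA-seq of the mock-treated RNA, with 3 libraries in each of 5 groups. Library totals ran from 3806556 to 9097552 counts for mock mRNA, 16707841 to 19798778 for mock SPAAC, 10720005 to 15932443 for mock CuAAC, 13659501 to 15232302 for m7G-depleted SPAAC and 6242770 to 7056230 for m7G-depleted CuAAC.

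Organelle RNA and 18S rRNA took far smaller shares of the captured libraries than of mRNA-seq. Chloroplast-encoded genes held 7.69 ± 0.899% of mRNA-seq counts (SD, n = 3), 0.172 ± 0.00474% in mock SPAAC and 0.348 ± 0.0481% in mock CuAAC. After m7G depletion the shares were 0.704 ± 0.177% in SPAAC and 1.75 ± 0.331% in CuAAC. Mitochondria-encoded genes held 2.56 ± 0.0992% of mRNA-seq counts, 0.114 ± 0.00928% in mock SPAAC, 0.140 ± 0.00729% in mock CuAAC, 0.456 ± 0.0234% in m7G-depleted SPAAC and 0.714 ± 0.0759% in m7G-depleted CuAAC. A share weighs abundant genes most, and this drop is larger than that of most mitochondria-encoded genes. In mock SPAAC against mRNA-seq the 78 tested had a median log2 fold change of -1.20, and 42 were not called. ATMG01390, named after its values were seen, had 16110 ± 1691 CPM in mRNA-seq and 270 ± 23.3 CPM in mock SPAAC. The 18S rRNA gene AT3G41768 took 26.2 ± 5.08% of mRNA-seq counts, 0.320 ± 0.0284% in mock SPAAC and 0.574 ± 0.0302% in mock CuAAC. The 2-sided exact permutation p was 0.1 for each pair of groups compared below, the smallest value that 3 against 3 libraries can give. Leaving out the 20 most abundant genes moved the mitochondrial share in mRNA-seq from 2.56% to 4.21%, the latter a share of the smaller total that is left.

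**Figure D1:**
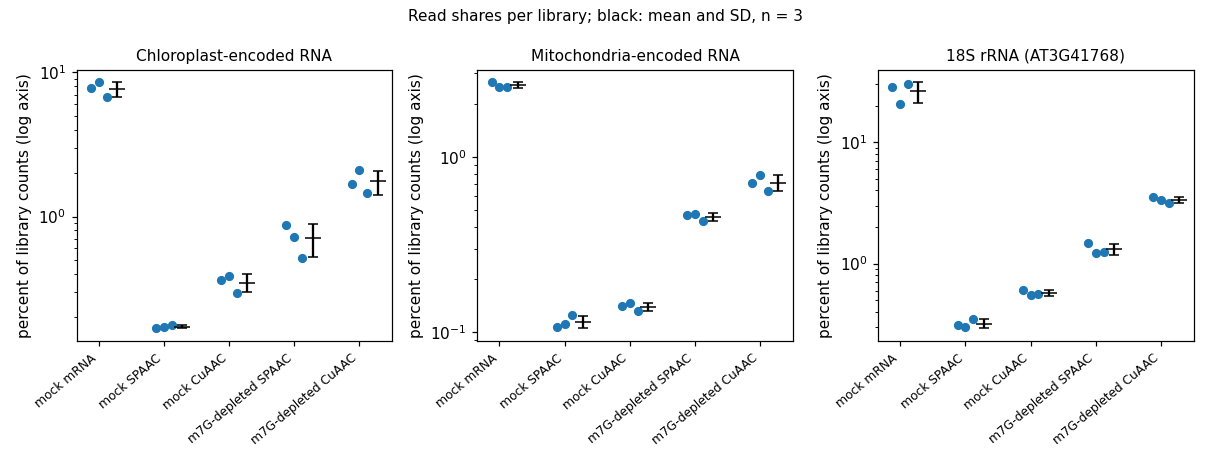
Percent of library counts (log axis) on chloroplast-encoded genes, mitochondria-encoded genes and 18S rRNA; blue points are libraries, and black marks are the mean and SD of 3 libraries per group. In all 3 panels the mock SPAAC mean is the lowest (0.172%, 0.114% and 0.320%) and the mRNA mean the highest (7.69%, 2.56% and 26.2%).

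The comparison of mock SPAAC with mock mRNA asked which transcripts the copper-free capture enriches. All 115 tested chloroplast-encoded genes were called lower, with a median log2 fold change of -5.67. ATCG00450 went from 141 ± 7.53 CPM in mRNA-seq to 0.65 ± 0.16 CPM, a log2 fold change of -7.72 ± 0.34. Of 78 mitochondria-encoded genes, 36 were lower, among them ATMG00020 at -6.29 ± 0.13 and ATMG00030 at -5.96 ± 0.12. Both organelle lists passed the camera test, and both calls held with an estimated correlation (adjusted p = 0.00435 and 0.035). Adjusted over the list alone, 2 mitochondria-encoded genes were higher and 37 lower, and the counts of the other lists were the same as over all genes.

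Among nuclear genes, AT7SL-1 (AT4G02970), an RNA of the signal recognition particle, was lower by -7.33 ± 0.41. AT2G09250, a non-coding gene on chromosome 2 (17224503 to 17224801, TAIR10.1), was lowest at -9.00 ± 0.26. It lies inside the cytokinin response regulator gene RR3 on the opposite strand (-6.89 ± 0.17), and in mRNA-seq both had close to equal levels, 448 ± 59 and 453 ± 59 CPM, so the reads cannot be assigned to either gene. The reads counted for AT2G09250 made up 99.0 ± 0.0656% of those of RR3 in mRNA-seq and 22.8 ± 3.47% in mock SPAAC. In a count chosen after the data were seen, the RR3 reads outside AT2G09250 gave -0.63 ± 0.30 (adjusted p = 0.119), which was not called. Of 27 cytosolic ribosomal protein genes 11 were lower, including RPS10B (-1.85 ± 0.11) and RPL5B (-1.67 ± 0.12). That list passed with the preset correlation (adjusted p = 6.2e-17) and not with an estimated correlation (adjusted p = 0.13, and 0.021 with the replicate block added). Of 19 very large protein genes, 9 were lower, led by AT2G17930 (-2.01 ± 0.21) and AT4G36080 (-1.93 ± 0.13; list adjusted p = 1.1e-13, and adjusted p = 0.16 with an estimated correlation). Of 39 photosystem and light-harvesting genes, 4 were lower, among them the paralogs CAB2 (-2.78 ± 0.10) and CAB3 (-2.56 ± 0.19), whose reads may be shared between copies, which was not tested. The list p was 0.033 toward lower values, the adjusted p was 0.76 with an estimated correlation, and with library totals in place of TMM the list turned toward higher values without passing (adjusted p = 0.518), with 9 members higher and 3 lower. Library totals also left 1 ribosomal protein gene lower, with 2 higher, and 3 very large protein genes lower, and offsets that remove each library's trend with length and GC left 1 very large protein gene lower. RPL5B was at -0.97 with library totals, and AT2G17930 and AT4G36080 at -0.88 and -0.81 with the offsets, which ended these 3 calls. With library totals RPS10B, AT2G17930 and AT4G36080 were at -1.14, -1.29 and -1.22.

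Genes higher in SPAAC than in mRNA-seq changed by smaller amounts. The ubiquitin protease gene UBP7 (AT3G21280) rose from 7.9 ± 2.24 to 24.8 ± 0.18 CPM (1.72 ± 0.16), AT3G53590 rose by 1.60 ± 0.14, AT5G07710 by 1.59 ± 0.27 (1.03 without mock mRNA replicate 1) and AT3G10120 by 1.56 ± 0.27. UBP7, AT3G53590 and AT3G10120 overlap an opposite-strand gene. In carbon fixation, the Rubisco small subunit gene RBCS2B was higher (1.16 ± 0.13) and CP12-2 lower (-1.57 ± 0.28). The superoxide dismutase gene FSD1 was lower (-1.43 ± 0.11), as was the cold-response gene COR15A (-1.72 ± 0.49, adjusted p = 0.020), a call that ended without mock SPAAC replicate 2 or 3 or mock mRNA replicate 1 (adjusted p = 0.068, 0.057 and 0.087). The translation factor gene AT5G60390 of the reference list was lower (-1.54 ± 0.09). The clock gene PRR7 (-0.82 ± 0.11), XRN4 of the decapping list (0.46 ± 0.10), AOS of the jasmonate list (0.33 ± 0.11) and PYK10 of the root list (0.65 ± 0.08) did not reach the fold threshold. Of 14 jasmonate and 10 root genes 1 each was called, at a mean under 10 CPM and named after its values were seen: the defensin gene PDF1.2 was lower (-2.29 ± 0.34), as was the Casparian strip gene CASP1 (-1.58 ± 0.22; -0.85 with library totals and adjusted p = 0.0626 by glmTreat, which ended its call). The lists of antioxidant, carbon fixation, clock, cold, jasmonate, NAD metabolism, reference and root genes gave adjusted p from 0.32 to 0.92. With library totals the antioxidant, carbon fixation and reference lists passed toward higher values (adjusted p = 0.00746, 0.00214 and 0.00286), the calls of FSD1 (-0.72), CP12-2 (-0.85), COR15A (-0.98, adjusted p = 0.092) and AT5G60390 (-0.83) ended, XRN4 (1.19), AOS (1.045) and PYK10 (1.37) were called, and RBCS2B and PRR7 were at 1.865 and -0.11. By glmTreat against a fold of 2 the calls of AT5G07710, AT3G10120, RBCS2B, CP12-2 and COR15A ended (adjusted p from 0.239 to 0.947). The cytokinin list, which holds RR3, passed with the replicate block (adjusted p = 0.019 against 0.32 without).

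By edgeR, 407 genes were higher and 1109 lower in SPAAC than in mRNA-seq. With library totals in place of TMM the counts were 6901 higher and 356 lower, and the median log2 fold change of all genes moved from 0.07 to 0.80. Nuclear protein-coding genes held 96.3 ± 0.0698% of mock SPAAC counts and 60.4 ± 4.25% of mRNA-seq counts. Library totals leave this difference in composition in the fold changes. By glmTreat against a fold of 2, 10 genes were higher and 437 lower.

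In the comparison of mock CuAAC with mock mRNA, organelle RNA and long transcripts were lower. All 115 chloroplast genes were lower (median -5.10, adjusted p = 0.025 with an estimated correlation), with ATCG00630 at -7.32 ± 0.61 and ATCG00220 at -6.59 ± 0.50. Of 78 mitochondria-encoded genes 48 were lower and 2 higher (median -2.14, adjusted p = 0.043 with an estimated correlation). All 19 very large protein genes were lower, with a median of -2.42, and that list call held with an estimated correlation (adjusted p = 0.025). AT2G17930 fell from 79.9 ± 7.3 to 7.29 ± 2.8 CPM (-3.44 ± 0.23) and AT4G36080 changed by -3.37 ± 0.15. With length and GC offsets 2 of the 19 were lower, AT2G17930 was at -1.05, and the call of AT4G36080 ended (-0.97).

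Genes higher in CuAAC had a median length of 1231 nt, against 2068 nt for those lower. The RING finger gene RHA1B (AT4G11360) rose from 64.9 ± 0.62 to 269 ± 40 CPM (2.05 ± 0.11), and SIB1, which encodes a sigma factor binding protein, rose by 2.03 ± 0.20. AT1G05933 (2.47 ± 0.23, and 3.095 without mock mRNA replicate 1) overlaps an opposite-strand gene, and AT2G35470 rose by 2.03 ± 0.13. Of 14 antioxidant genes 3 were higher, with GPX1 at 1.29 ± 0.09 and DHAR1 at 1.14 ± 0.10 (list adjusted p = 0.0012, and adjusted p = 0.043 with an estimated correlation). Of 16 carbon fixation genes 3 were higher, with RBCS2B at 1.51 ± 0.13 and RBCS3B at 1.32 ± 0.09 (list adjusted p = 0.0081, and adjusted p = 0.51 with an estimated correlation). In the photosystem list 1 gene was higher and 3 lower, the median was 0.35, and the list p of 0.012 became an adjusted p of 0.73 with an estimated correlation. CAB2 (-2.44 ± 0.10) and CAB3 (-2.15 ± 0.19) were lower again. Of 27 ribosomal protein genes 11 were lower, with RPS10B at -1.55 ± 0.11 (list adjusted p = 3.7e-05, and adjusted p = 0.43 with an estimated correlation). With library totals 0 ribosomal protein genes were lower and 5 higher (21 past the adjusted p alone, median 0.06, and list adjusted p = 0.0824 toward lower values), 17 photosystem genes were higher and 3 lower, and 8 antioxidant and 6 carbon fixation genes were higher.

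Other members were PRR7 (-1.55 ± 0.11), RR3 (-6.03 ± 0.17, and -1.26 ± 0.33 by the reads outside AT2G09250), P5CS1 of the cold list (-1.33 ± 0.34), AT5G60390 (-1.37 ± 0.09) and the aquaporin gene TIP2;3 of the root list (1.61 ± 0.25). COR15A was at -1.36 ± 0.49 (adjusted p = 0.042), and its call ended without mock CuAAC replicate 2 or 3 or mock mRNA replicate 1 or 3 (adjusted p = 0.13, 0.079, 0.17 and 0.085), as it did with library totals, without the low-count filter and with the compared groups alone (adjusted p = 0.207, 0.061 and 0.072). Library totals ended the calls of PRR7 (-0.95), RPS10B (-0.95), P5CS1 (-0.71, adjusted p = 0.082) and AT5G60390 (-0.77), called VSP1 (1.03), put DHAR1 at 1.75, and took the reference list past the threshold toward higher values (adjusted p = 0.00221). Length and GC offsets ended the calls of P5CS1 (-0.89, adjusted p = 0.065) and GPX1 (0.89), and glmTreat those of DHAR1, P5CS1, COR15A and TIP2;3 (adjusted p from 0.0636 to 0.762). DCP2 (-0.62 ± 0.14) and VSP1 (0.42 ± 0.18) were not called. Of the 14 jasmonate genes PDF1.2, under 10 CPM and named after its values were seen, was the only call and was lower (-2.07 ± 0.34, and -1.48 without mock mRNA replicate 1). Cold and cytokinin genes passed as lists only with the replicate block (adjusted p = 0.021 and 0.044, against 0.45 and 0.33). The clock, jasmonate, NAD metabolism, reference and root lists gave adjusted p from 0.145 to 0.509. The counts of all 14 lists were the same when adjusted over the list alone. By edgeR, 1093 genes were higher and 2405 lower. With library totals the counts were 5599 higher and 1012 lower, with a median shift from 0.01 to 0.62, and glmTreat called 144 higher and 1084 lower.

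The lists of enriched transcripts from both chemistries shared 285 genes, 70% of the SPAAC list and 26.1% of the CuAAC list. Independent lists would share 20.7, and unchanged groups simulated with shared mRNA libraries, themselves simulated, shared 0. With no change simulated few genes can be called, so that 0 is no bound on chance. Nor is the 20.7, since both comparisons share their mRNA libraries. Of the genes lower than mRNA-seq, 784 were shared, against 124.3 for independent lists. The higher genes shared numbered 4028 with library totals, 188 with the filter of 5 CPM, 187 with the compared groups alone and 9 by glmTreat, settings chosen for this count after the data were seen. Across 10920 genes the fold changes correlated at 0.81 (simulated 0.57), with a covariance of 0.54 against 0.016 simulated; genes are not independent replicates. Part of the excess may come from the shared mRNA libraries, which are too few to split.

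SPAAC was compared with CuAAC directly to test the chemistries on the same RNA. Long transcripts were higher in SPAAC: 18 of 19 very large protein genes were called, with a median of 1.35, among them emb1507 (1.86 ± 0.15) and NRPB1, the largest subunit of RNA polymerase II (94.8 ± 5.7 against 32.1 ± 2.3 CPM, 1.56 ± 0.13). The list adjusted p was 3.9e-27 with the preset correlation, 0.053 with an estimated correlation and 0.021 with the replicate block added. Length and GC offsets left 0 of the 19 called by edgeR (5 past the adjusted p alone, median 0.15), with emb1507 at 0.82 and NRPB1 at 0.56. Nuclear coding genes of up to 500 nt had a median log2 fold change of -0.38 (70 genes), and those over 5000 nt had 1.03 (253 genes). The Spearman correlation with length across all tested genes was 0.56, and with GC content 0.16. Genes are not independent replicates here.

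The genes with the largest rise in SPAAC were AT4G05631 (29 ± 1.8 against 1.41 ± 0.18 CPM, 4.37 ± 0.18), AT4G16955 (3.71 ± 0.21), AT1G29680 (3.16 ± 0.18) and AT4G27790 (3.14 ± 0.13). AT4G16955, AT1G29680 and AT4G27790 overlap an opposite-strand gene. Among called genes with a mean CPM of at least 5, 22 of the 30 highest (73.3%) overlap a more abundant opposite-strand gene. Of all 14435 tested genes at that level, 13% do. Strands were not separated, so these values may hold reads of the neighbouring gene. AT2G01010, annotated as rRNA, was lowest (-2.74 ± 0.33), followed by AT2G09250 (-2.53 ± 0.29). Of 115 chloroplast genes 23 were lower, with the 16S rRNA gene ATCG00920 at -2.08 ± 0.27 and the Rubisco large subunit gene ATCG00490 at -1.71 ± 0.15 (list adjusted p = 3.3e-10, and adjusted p = 0.49 with an estimated correlation). Of 78 mitochondria-encoded genes 17 were higher, with ATMG00513 at 1.93 ± 0.14, and 2 lower. That list p of 0.046 became an adjusted p of 0.63 with an estimated correlation, an adjusted p of 0.074 with the replicate block and an adjusted p of 0.109 with library totals. The cold-response gene LTI78 was higher (1.21 ± 0.08), a call that ended with length and GC offsets (0.81) and by glmTreat (adjusted p = 0.0869).

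The photosystem list had no called member and a median of -0.42, with PSAF at -0.73 ± 0.10 (list adjusted p = 7.4e-10, and adjusted p = 0.38 with an estimated correlation). The antioxidant, carbon fixation and ribosomal lists had no called member and medians of -0.42, -0.27 and -0.21 (preset adjusted p = 0.0019, 0.0092 and 0.00087). Their estimated-correlation adjusted p were 0.051, 0.51 and 0.52, the first of which was 0.021 with the replicate block added. DHAR1 (-0.67 ± 0.10), FBA2 (-0.37 ± 0.09) and the ribosomal gene PFL (-0.59 ± 0.10) had the smallest adjusted p of their lists. XRN4 (0.66 ± 0.09), GI (0.64 ± 0.08), HK3 (0.62 ± 0.08), VSP1 (-0.46 ± 0.16), GAPC2 (-0.34 ± 0.07) and TIP2;2 (-0.78 ± 0.10) were under the fold threshold. Of 17 cytokinin genes 1 was called, the receptor gene WOL, under 10 CPM and named after its values were seen (1.17 ± 0.21). Its call ended without mock CuAAC replicate 3 (0.96), with length and GC offsets (0.34, adjusted p = 0.320) and by glmTreat (adjusted p = 1). XRN4, GI and HK3 changed sign with length and GC offsets (-0.03, -0.21 and -0.26). The cold list passed with the replicate block (adjusted p = 0.022 against 0.145), and the cytokinin, clock, jasmonate, NAD metabolism, reference and root lists gave adjusted p from 0.147 to 0.965. The mitochondrial list had 16 genes higher when adjusted over the list alone, and the other list counts were the same. By edgeR 1388 genes were higher and 109 lower. The number higher was 729 with length and GC offsets and 385 by glmTreat, and the number lower was 177 without mock CuAAC replicate 2.

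**Figure D2:**
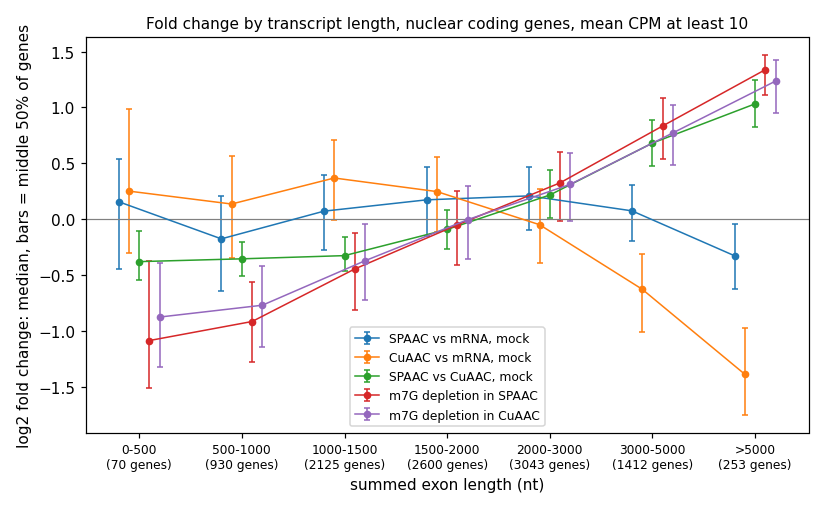
Median log2 fold change (points, with the middle 50% of genes as bars) by summed exon length in nt for nuclear coding genes with mean CPM of at least 10. The SPAAC over CuAAC median goes from -0.38 in the shortest class to 1.03 in the longest.

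Depletion with the m7G antibody was compared with mock treatment in SPAAC libraries to see which transcripts depend on m7G-capped RNA. Organelle transcripts and long transcripts rose: 104 of 115 chloroplast genes (median 2.14), 77 of 78 mitochondria-encoded genes (median 2.08) and all 19 very large protein genes (median 1.48). ATCG01020 rose from 9.72 ± 1.6 to 73.7 ± 59 CPM (2.92 ± 0.50, and 2.04 without m7G-depleted SPAAC replicate 1), ATCG01090 by 2.92 ± 0.35, ATMG01170 by 2.37 ± 0.13 and ATMG01130 by 2.31 ± 0.18. ILA rose from 51.6 ± 4.7 to 163 ± 14 CPM (1.66 ± 0.15), and AT2G17930 rose by 1.62 ± 0.20. Offsets for length and GC left 0 of the 19 very large protein genes called by edgeR (4 past the adjusted p alone, median 0.13), with ILA at 0.31 and AT2G17930 at 0.18 (adjusted p = 0.252). The mitochondrial list held with an estimated correlation (adjusted p = 0.025), and the chloroplast and very large lists did not (adjusted p = 0.23 and 0.076), the latter at an adjusted p of 0.023 with the replicate block added.

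Genes that fell had a median length of 985 nt, against 3412 nt for those that rose. The metallothionein gene MT3 fell from 724 ± 75 to 128 ± 9.5 CPM (-2.50 ± 0.09), together with AT3G03105, which overlaps it. AT3G11120 (-2.64 ± 0.33) and AT2G05510 (-2.48 ± 0.21) also fell. Of 39 photosystem genes 17 were lower, led by PSAK (-1.89 ± 0.09) and PSAL (-1.82 ± 0.09), subunits of photosystem I (list p = 8e-16, and adjusted p = 0.25 with an estimated correlation). Of 16 cold genes 7 were lower, with AT5G66400 at -1.74 ± 0.52 and COR47 at -1.57 ± 0.08 (list adjusted p = 2.1e-05, and adjusted p = 0.076 with an estimated correlation and 0.021 with the replicate block added). The AT5G66400 call ended without m7G-depleted SPAAC replicate 2 or mock SPAAC replicate 1 (adjusted p = 0.057 and 0.062). Of 14 antioxidant genes 4 were lower, with TRX3 at -1.28 ± 0.09 and CSD2 at -1.18 ± 0.19 (adjusted p = 0.043 with an estimated correlation). With length and GC offsets 7 photosystem genes were lower and 1 higher, 4 cold and 0 antioxidant genes were lower (10 antioxidant genes past the adjusted p alone), PSAK was at -1.155, and the calls of AT5G66400 (-1.09, adjusted p = 0.09), TRX3 (-0.55) and CSD2 (-0.60) ended. With the offsets and the replicate block AT5G66400 was past the thresholds (-1.09, adjusted p = 5.6e-38 by edgeR). The edgeR adjusted p of PSAK went from 7.8e-09 with the offsets to 2.2e-36 with the block added. With 3 libraries per group, p-values this small cannot come from the spread of single genes. They are therefore no support for the AT5G66400 call.

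RBCS3B (-1.10 ± 0.09) and RBCS1B (-1.09 ± 0.11) were lower in a carbon fixation list that did not pass (adjusted p = 0.41). AT3G53890 (-1.39 ± 0.10) and RPS10B (-1.35 ± 0.11) were lower in the ribosomal list (p = 5.3e-05, and adjusted p = 0.45 with an estimated correlation). The decapping scaffold gene VCS rose (1.27 ± 0.09), with its list at p = 0.025 and adjusted p = 0.19 with an estimated correlation. ELF4 was lower (-1.35 ± 0.27) although 3 of 12 clock genes were higher and 1 lower (list p = 0.015, and adjusted p = 0.11 with an estimated correlation). RR3 (1.09 ± 0.17), VSP2 (-1.90 ± 0.56) and IRT1 (-1.09 ± 0.22) were called, and AT1G07940 (0.72 ± 0.08) was not. By its reads outside AT2G09250 RR3 was at 0.38 ± 0.25 (adjusted p = 0.220) and not called. The VSP2 call ended without m7G-depleted SPAAC replicate 2 or mock SPAAC replicate 1 (adjusted p = 0.055 and 0.053). The fold change went under the threshold for RBCS1B without m7G-depleted SPAAC replicate 3 (-0.999), for RR3 without m7G-depleted SPAAC replicate 1 or mock SPAAC replicate 2 (0.96 in both) and for IRT1 without m7G-depleted SPAAC replicate 2 or mock SPAAC replicate 1 (-0.92 and -0.87). The offsets ended the calls of RBCS3B (-0.85), AT3G53890 (-0.58), RPS10B (-0.74), VCS (0.26), ELF4 (-0.64, adjusted p = 0.066), RR3 (0.90) and IRT1 (-0.94), and 0 ribosomal protein genes were lower (16 past the adjusted p alone) and 0 clock genes higher and 1 lower (6 past the adjusted p alone in either direction). The lower one was PCL1, at -1.68 with the offsets and -0.89 without, named after its values were seen. By glmTreat the calls of CSD2, RBCS3B, RBCS1B, ELF4, AT5G66400, RR3, VSP2 and IRT1 ended (adjusted p from 0.295 to 0.986). The root list passed with the replicate block (adjusted p = 0.047 against 0.11), and the cytokinin, jasmonate and reference lists gave adjusted p from 0.322 to 0.615. Adjusted over the list alone, 105 chloroplast genes rose, and the other list counts were the same. By edgeR 1582 genes were higher and 2073 lower, and with length and GC offsets 561 were higher and 798 lower.

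Depletion in CuAAC libraries was then compared with mock treatment, and organelle and very large protein genes rose. Of 115 chloroplast genes 101 rose (median 2.18, adjusted p = 0.16 with an estimated correlation), with ATCG01080 at 2.64 ± 0.39. Of 78 mitochondria-encoded genes 72 rose (median 2.12, adjusted p = 0.025 with an estimated correlation), with ATMG00020 at 2.49 ± 0.11. Of 19 very large protein genes 18 rose, with AT4G36080 at 1.76 ± 0.16 (adjusted p = 0.067 with an estimated correlation, and 0.024 with the replicate block added). AT7SL-1 rose by 3.40 ± 0.62, AT2G09250 by 2.93 ± 0.21 and the rRNA gene AT2G01010 from 14.3 ± 1.9 to 90.1 ± 7.6 CPM (2.65 ± 0.27). AT1G67860 (-2.23 ± 0.18), AT1G27330 (-2.19 ± 0.18), AT1G13930 (-2.19 ± 0.09) and AT4G37240 (-2.17 ± 0.24) fell. Of 39 photosystem genes 14 were lower (PSAK at -1.69 ± 0.09), of 16 cold genes 4 (COR47 at -1.37 ± 0.08) and of 14 antioxidant genes 3 (PRXQ at -1.14 ± 0.08). Their adjusted p with an estimated correlation were 0.31, 0.093 and 0.053, against 4.2e-12, 0.00011 and 0.0032 with the preset value, and the cold and antioxidant lists were both at 0.021 with the replicate block added. Under length and GC offsets 0 very large protein genes were called by edgeR (6 past the adjusted p alone, median 0.19, AT4G36080 at 0.37), 5 photosystem genes were lower and 2 higher, 4 cold and 0 antioxidant genes were lower (9 antioxidant genes past the adjusted p alone), PSAK was at -1.02 and PRXQ at -0.85.

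The clock list (p = 0.032), the ribosomal list (p = 0.0092) and the NAD metabolism list (p = 0.019) passed with the preset correlation, and not with an estimated correlation (adjusted p = 0.16, 0.63 and 0.16). Their median log2 fold changes were 0.55, -0.13 and 0.41, and of 12 clock genes 2 were higher and 1 lower. ELF4 (-1.51 ± 0.29), AT3G53890 (-1.23 ± 0.11), VCS (1.21 ± 0.09), RR3 (2.58 ± 0.16) and IRT1 (-1.09 ± 0.24) were called, RR3 not by its reads outside AT2G09250 (0.66 ± 0.32, adjusted p = 0.0951). VSP2 was called (-1.82 ± 0.59, adjusted p = 0.025), and the call ended without m7G-depleted CuAAC replicate 2 or 3 or mock CuAAC replicate 1 or 3 (adjusted p = 0.081, 0.055, 0.082 and 0.059). Without mock CuAAC replicate 1 the fold change of IRT1 was -0.91, under the threshold. The offsets ended the calls of ELF4 (-0.85), AT3G53890 (-0.45), VCS (0.27), IRT1 (-0.955) and VSP2 (-1.63, adjusted p = 0.0503), and the call of VSP2 ended also with the compared groups alone (adjusted p = 0.060). Under the offsets 0 ribosomal protein genes were lower by edgeR (15 past the adjusted p alone), and the median of that list moved from -0.13 to 0.17. PCL1, named after its values were seen, was called lower there (-1.57, and -0.89 without the offsets). By glmTreat the calls of PRXQ, ELF4, AT3G53890, VCS, VSP2 and IRT1 ended (adjusted p from 0.104 to 1). PRK (-0.93 ± 0.08) and AT1G07940 (0.71 ± 0.08) were not called. The reference and root lists passed with the replicate block (adjusted p = 0.011 and 0.017, against 0.091 and 0.054), the root list also with library totals (adjusted p = 0.0485), and the carbon fixation, cytokinin and jasmonate lists gave adjusted p of 0.62, 0.45 and 0.56. Adjusted over the list alone, 105 chloroplast, 73 mitochondria-encoded and 3 clock genes rose, 5 cold and 0 jasmonate genes fell (1 over all genes), and the other list counts were the same. By edgeR 1357 genes were higher and 1767 lower, and with length and GC offsets 512 were higher and 760 lower.

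**Figure D3:**
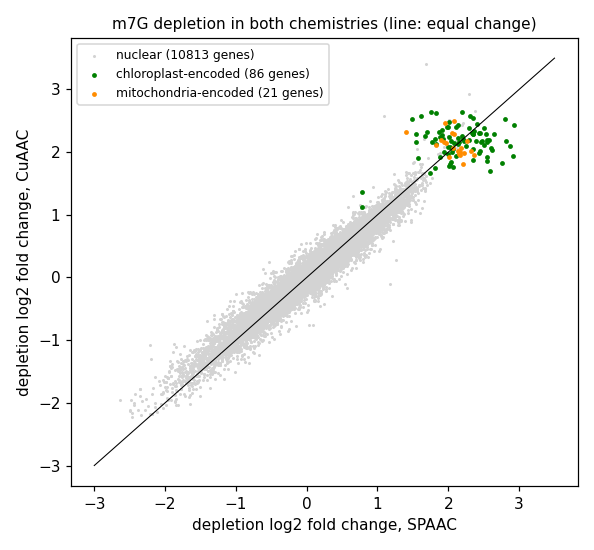
Log2 fold change under m7G depletion in SPAAC (x axis) and CuAAC (y axis) for genes with mean CPM of at least 10; green and orange points are organelle genes, and the line marks equal change. Across 10920 genes the correlation was 0.97.

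The interaction asked whether depletion acted differently in the 2 chemistries. RR3 was the only gene called by edgeR: it rose by 1.09 ± 0.17 in SPAAC and 2.58 ± 0.16 in CuAAC, an interaction of -1.50 ± 0.23 (adjusted p = 0.036). The reads of AT2G09250 made up 92.8 ± 0.349% of those of RR3 in depleted CuAAC and 51.9 ± 9.16% in depleted SPAAC, and by the reads outside it RR3 had an interaction of -0.28 ± 0.41 (adjusted p = 0.9999). Across 10920 genes the depletion effects correlated at 0.97 with a slope of 0.92, 1051 genes were called higher in both and 1332 lower in both, and 0 were called in opposite directions. By edgeR 0 genes were higher and 1 lower, with 828 genes at an unadjusted p under 0.05. DESeq2 called 1 higher and 2 lower, and the replicate block 2 and 2. The RR3 call ended without m7G-depleted CuAAC replicate 1 or 2, m7G-depleted SPAAC replicate 2 or 3, mock CuAAC replicate 2 or 3, or mock SPAAC replicate 1 or 3, with adjusted p from 0.0949 to 0.196. It also ended with library totals, TMM on nuclear genes, the filter of 5 CPM, the compared groups alone and glmTreat (adjusted p = 0.187, 0.056, 0.066, 0.055 and 1). In the lists, adjusted over the list alone, RR3 was again the only call.

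After depletion the chemistries were compared again. AT4G05631 (4.14 ± 0.16) and AT5G55660 (3.25 ± 0.21) were highest, and AT2G09250 (-3.18 ± 0.21) and AT2G01010 (-3.02 ± 0.28) lowest. Of 19 very large protein genes 16 were higher (list adjusted p = 1.8e-27, and adjusted p = 0.053 with an estimated correlation and 0.021 with the replicate block added), and 0 by edgeR with length and GC offsets (6 past the adjusted p alone, median 0.07). Of 115 chloroplast genes 25 were lower and 1 higher (list adjusted p = 2e-12, and adjusted p = 0.42 with an estimated correlation). The photosystem list had no called member and a median of -0.63 (list adjusted p = 1.1e-18, and adjusted p = 0.20 with an estimated correlation). No list count changed when adjusted over the list alone. By edgeR 1566 genes were higher and 192 lower. The reference list passed only with the replicate block (adjusted p = 0.049 against 0.15).

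Depleted SPAAC was then compared with mock mRNA-seq. AT2G07774 (3.34 ± 0.16) and AT2G07695 (3.31 ± 0.20) were highest, and AT2G09250 (-6.71 ± 0.22) and RR3 (-5.81 ± 0.16, and -0.26 ± 0.30 with adjusted p = 0.494 by the reads outside AT2G09250) lowest. With depletion AT2G07774 rose from 15.8 ± 3.2 to 64.0 ± 5.5 CPM in SPAAC, where the mitochondrial share rose by 3.99 times. Whether the reads of AT2G07774 and AT2G07695 come from mitochondrial RNA was not tested, so both values are uncertain. Of 115 chloroplast genes 112 were lower (adjusted p = 0.043 with an estimated correlation), and of 27 ribosomal protein genes 19 were lower (list adjusted p = 1.9e-20, and adjusted p = 0.091 with an estimated correlation and 0.021 with the replicate block added), 7 with length and GC offsets and 4 with library totals. Of 78 mitochondria-encoded genes 35 were higher and 17 lower, with a median of 0.99 and a list that did not pass (adjusted p = 0.327). With library totals 49 were higher and 9 lower. Adjusted over the list alone, 113 chloroplast genes were lower, and the other list counts were the same. By edgeR 2340 genes were higher and 2959 lower (8641 and 985 with library totals, median shift from 0.06 to 0.82). The cold list, toward lower values, had adjusted p = 0.00091, 0.16 with an estimated correlation and 0.033 with the replicate block added. The NAD metabolism and antioxidant lists passed with the replicate block (adjusted p = 0.046 and 0.0076, against 0.058 and 0.055), and the NAD metabolism and reference lists passed with library totals (adjusted p = 0.0167 and 0.00153).

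In depleted CuAAC against mock mRNA-seq the extremes were AT2G07695 (3.96 ± 0.20) and AT2G07774 (3.71 ± 0.16) at the top and ATCG00630 (-5.08 ± 0.55) and AT7SL-1 (-4.94 ± 0.37) at the bottom. The origin of the reads of AT2G07695 and AT2G07774 is uncertain here too. Of 115 chloroplast genes 109 were lower (list adjusted p = 2.4e-69, and adjusted p = 0.053 with an estimated correlation), and of 16 cold genes 10 were lower (list adjusted p = 4.9e-06, and adjusted p = 0.066 with an estimated correlation and 0.021 with the replicate block added), 2 with library totals. The ribosomal list, toward lower values, had adjusted p = 5.55e-12, 0.20 with an estimated correlation and 0.024 with the replicate block added. Of 78 mitochondria-encoded genes 22 were higher and 24 lower, with a median of 0.11 and a list test toward lower values that did not pass (adjusted p = 0.541). With library totals 33 were higher and 16 lower. Adjusted over the list alone, 111 chloroplast and 11 cold genes were lower, 23 mitochondria-encoded genes were higher against 22 over all genes, and the other list counts were the same. By edgeR 1157 genes were higher and 2698 lower (5723 and 1067 with library totals, median shift from -0.02 to 0.61). Both comparisons of depleted libraries with mRNA-seq differ in both capture and depletion.

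Of the 407 genes higher than mRNA-seq in mock SPAAC, 207 (50.9%) were also higher after depletion, with 2133 further genes. Of the 1093 in mock CuAAC, 375 (34.3%) were also higher, with 782 further genes. Independent lists would share 44.4 and 58.9 genes, and unchanged groups with shared simulated mRNA libraries shared a mean of 0 and 0.05. With length and GC offsets the shares were 57.8% and 49.0%, with 1034 and 859 further genes, and with library totals they were 65.6% and 52.9%, with 4117 and 2762 further genes. The depleted chemistries shared 751 higher genes, against 126.2 for independent lists and 0 for unchanged groups with shared simulated mRNA libraries. For the kept genes and for those shared after depletion, neither value is a bound on chance where both comparisons hold effects and share their mRNA libraries, so part of the excess may come from those libraries. With library totals 4775 were shared, and by glmTreat 146.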

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

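The interaction test of depletion by chemistry, a planned test, passed at adjusted p alone for 3 genes, and for 4 gene lists with the preset correlation and 0 with an estimated correlation (adjusted p from 0.16 to 0.31); the count over other splits and the count of RR3 reads outside AT2G09250 were chosen only after the result was seen, among the tests of this part. RR3 had an interaction log2 fold change of -1.50 (adjusted p = 0.036 by edgeR, and 0.055 with the compared groups alone). AT2G09250, on the opposite strand in the last exon of RR3, held 5.05 of 6.89 CPM in mock and 38.7 of 41.7 CPM in depleted CuAAC, and 0.863 of 3.81 CPM and 4.25 of 8.09 CPM in SPAAC. Outside it RR3 had 1.84 ± 0.943 and 3.01 ± 0.359 CPM in CuAAC and 2.95 ± 0.578 and 3.84 ± 0.716 CPM in SPAAC, an interaction of -0.28 ± 0.41 (adjusted p = 0.9999 by edgeR), and AT2G09250 itself had -0.64 ± 0.39 (adjusted p = 0.9999). TOC159, which encodes a chloroplast import receptor, had 0.64 (0.19 ± 0.07 in SPAAC, -0.45 ± 0.07 in CuAAC). The mitochondrial gene ATMG01390 had -0.91 (CPM of 270 ± 23.3 in mock and 713 ± 73.2 in m7G-depleted SPAAC, and 412 ± 26.7 and 2051 ± 244 in CuAAC). TOC159 and ATMG01390 are under the fold threshold.

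The photosystem list had a median interaction of -0.21, the cytosolic ribosomal list -0.20, the carbon fixation list -0.20 and the antioxidant list -0.11. With length and GC offsets, under which the list tests were not run, the medians were -0.12, -0.15, -0.15 and -0.10, and the interaction correlated with length at 0.336 across genes with a mean CPM of at least 10. Their camera adjusted p were 5.9e-12, 3.9e-08, 4.1e-07 and 0.046 with the preset correlation, and 0.31, 0.30, 0.22 and 0.16 with an estimated correlation. The antioxidant list also missed the threshold with library totals (adjusted p = 0.05). With the replicate block and an estimated correlation the ribosomal, antioxidant and cold lists passed (adjusted p = 0.029, 0.049 and 0.049); the cold list was at 0.389 without the block. The cold, clock and reference lists passed with the replicate block alone (adjusted p = 6.1e-05, 0.037 and 0.047). Fitted on the compared libraries alone, the interaction had 0 calls by edgeR (1090 genes at an unadjusted p under 0.05), against 1 with all libraries and 3 by DESeq2. A count of 0 is reached by any regrouping of the depletion labels (40 of 40 drawn), so the regroupings say nothing about chance. The highest of the others gave 9654 calls. It exchanged the labels of all 3 CuAAC pairs and 0 of SPAAC, which puts the effect of depletion itself into the contrast by construction, and that is the structure of the samples it shows.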

How the results depend on the processing

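Outside the interaction, the balance of higher and lower counts held under most settings. With library totals it turned toward higher genes in every comparison with mRNA. It also turned so without the fold threshold in SPAAC and depleted SPAAC against mRNA and in both depletion comparisons, and by glmTreat for depletion in CuAAC. The alternatives for shared and kept genes given below, for called list members and for RR3 without the reads of AT2G09250 were chosen after the data were seen. All others were planned, and the cause was not tested of any change unless named. Over the alternatives, 2363 values of named genes kept their direction and call, 147 lost the call, 8 gained it and 6 changed sign. For gene lists these were 296, 55, 20 and 7. Of the counts, shares and trends, 735 stayed within a set limit, 269 moved past it and 2 changed sign. In the order SPAAC against mRNA, CuAAC against mRNA, SPAAC against CuAAC, depletion in SPAAC, depletion in CuAAC, SPAAC against CuAAC depleted, depleted SPAAC against mRNA and depleted CuAAC against mRNA, glmTreat called 10, 144, 385, 506, 333, 386, 657 and 258 higher and 437, 1084, 6, 528, 309, 17, 1503 and 1152 lower, a stricter test by construction. Without the fold threshold the counts were 3729, 4487, 4618, 5907, 5224, 4662, 6305 and 4577 higher and 3222, 5231, 3250, 5722, 4944, 3708, 5502 and 5094 lower. Library totals gave 6901, 5599, 8641 and 5723 higher and 356, 1012, 985 and 1067 lower against mRNA, and 63 and 113 lower in SPAAC against CuAAC, mock and depleted. The filter of 5 CPM gave 260 higher in SPAAC against mRNA, 925 higher and 49 lower in SPAAC against CuAAC, and 98 lower after depletion, with fewer genes tested.

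Length and GC offsets gave 729 and 753 higher in SPAAC against CuAAC (mock, depleted), 561 and 798 for depletion in SPAAC, 512 and 760 in CuAAC, and 1253 and 1702 for depleted SPAAC against mRNA. With the replicate block added these were 810 and 856, 620 and 881, 574 and 843, and 1344 and 1774; these fits hold no organelle genes and remove a length trend by construction. With the offsets XRN4, GI and HK3 changed sign in SPAAC against CuAAC (-0.0288, -0.21 and -0.256, and -0.0283, -0.21 and -0.254 with the replicate block). Members of the lists called only with the offsets numbered 1, 4, 1, 4, 6, 1, 10 and 8 in the order above, and 0 in the interaction. The interaction gave 0 lower by glmTreat, library totals, nuclear TMM, the 5 CPM filter, the compared groups alone and RR3 without the reads of AT2G09250, 2 without the low-count filter, 1 higher and 2 lower by DESeq2 and without a fold threshold, 2 and 2 with the replicate block, and 3 and 3 with the block and offsets. Leaving out each library gave 0 to 2 lower for the interaction and 105 to 177 lower for SPAAC against CuAAC. The replicate block without offsets changed no call of a named gene, and changed list calls only as given beside the results: 16 lists passed with an estimated correlation only when the block was added, and 0 lost that call.

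The higher genes shared by both chemistries (mock, depleted) numbered 4028 and 4775 with library totals and 9 and 146 by glmTreat, and in mock 188 with the filter of 5 CPM and 187 with the compared groups alone. The higher genes kept after depletion numbered 4524 in SPAAC and 2961 in CuAAC with library totals, 3 and 41 by glmTreat, and in SPAAC 129 with the filter of 5 CPM and 129 with the compared groups alone. Those found only after depletion numbered 4117 and 2762 with library totals, 654 and 217 by glmTreat, and in SPAAC 1034 with the offsets and 1057 with the offsets and the replicate block.

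Of the list tests 61 passed with the preset correlation, 11 with an estimated correlation and 27 with the block and an estimated correlation. Lists that changed sign were not past the threshold in the alternative: cold in SPAAC against mRNA with the replicate block (adjusted p = 0.451), mitochondria in the interaction with the block (0.812), and with library totals jasmonate (0.325, 0.826 and 0.5 in SPAAC, CuAAC and depleted CuAAC against mRNA), photosystem in SPAAC against mRNA (0.518) and carbon fixation in depleted SPAAC against mRNA (0.163). Without the 20 most abundant genes the chloroplast shares were 0.297%, 0.159% and 9.27% in mock CuAAC, SPAAC and mRNA, and the mitochondrial shares 0.903%, 0.531%, 0.166%, 0.132% and 4.21% in depleted CuAAC, depleted SPAAC, mock CuAAC, mock SPAAC and mRNA. All of these are shares of the smaller total that is left.

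The length correlation at a mean CPM of at least 10 was -0.407 for CuAAC against mRNA, 0.724 and 0.757 for SPAAC against CuAAC, 0.668 and 0.629 for depletion, 0.336 for the interaction, and 0.634 and 0.20 for depleted SPAAC and CuAAC against mRNA; with the 5 CPM filter it was -0.357 for CuAAC against mRNA, 0.659 and 0.679 for SPAAC against CuAAC, 0.624 and 0.586 for depletion, 0.25 for the interaction and 0.591 for depleted SPAAC against mRNA. The GC correlation at 10 CPM was -0.0755 and -0.174 for SPAAC and CuAAC against mRNA, 0.173 for SPAAC against CuAAC, 0.0679 for depleted SPAAC against mRNA and -0.0174 for depleted CuAAC against mRNA, where it changed sign; with the 5 CPM filter it was -0.0697 and -0.161 for SPAAC and CuAAC against mRNA, 0.0689 for depleted SPAAC against mRNA and -0.00365 for depleted CuAAC against mRNA, where it also changed sign. The mRNA libraries, with as few as 3806556 counts, limit the precision for weak genes.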

Other observations

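The tests of 3' loss in CuAAC, of GC content, of capped mRNA capture and of other splits were chosen only after the result was seen; the thinning tests and the depletion test on overlapping pairs were written down first.

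Against the same mRNA libraries, transcripts called higher in all 4 captured groups numbered 115, with a median length of 1649 nt, and 38 of them overlap an opposite-strand gene. They include AT2G07774 and AT2G07695, whose reads are of uncertain origin, and 55 of the 115 had a mean CPM of at least 10. AT5G07710, chosen after its values were seen, was higher by at least 1.59 on the log2 scale in each (1.03 for SPAAC without mock mRNA replicate 1). Transcripts lower in all 4 numbered 526, of which 109 were chloroplast-encoded and 17 mitochondria-encoded. No value for independent or unchanged groups was computed for either count, so part of the agreement may come from the shared mRNA libraries.

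Long transcripts were higher in SPAAC than in CuAAC. GC content is argued against as the whole cause, since the partial correlation with length given GC was 0.55, and so is depth, since thinning all 6 libraries to the lowest total among them, 10720005 counts, left 0.57. A candidate explanation is loss of 3' parts of transcripts in CuAAC. Weak genes that overlap the 3' end of an abundant gene (277) had a median SPAAC over CuAAC change 0.67 above that of weak genes at a 5' end (20; permutation p = 0.026, adjusted p = 0.079 over 9 comparisons). Top SPAAC over CuAAC genes prompted this test, and without the 30 highest, which removed 8 of the pairs, the difference was 0.63 (permutation p = 0.024, not adjusted). In depleted RNA the difference was 0.59 (permutation p = 0.036, adjusted p = 0.082), and 0.54 without those genes (permutation p = 0.054). In mock RNA, with a partner ratio of 5 or 20 in place of 10, it was 0.70 (permutation p = 3e-05) and 0.69 (permutation p = 0.12). Neither p was adjusted, and both values kept the top genes that prompted the test, so they do not decide. No biological explanation was tested because both chemistries used the same RNA.

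Long transcripts were also higher after m7G depletion. In SPAAC libraries the partial correlation with length given GC was 0.58 and the correlation after thinning was 0.56, which argue against GC and depth there. In CuAAC libraries the partial correlation was 0.54. Thinning was not run on them, so depth stays open for depletion in CuAAC. Uncapped 3' fragments that escape the antibody would raise the genes at a 3' end. Yet the difference was -0.22 in SPAAC (permutation p = 0.20) and -0.18 in CuAAC (permutation p = 0.22). For SPAAC it was -0.24 at a ratio of 5 (permutation p = 0.014) and -0.13 at a ratio of 20 (permutation p = 0.63). Against the change of the partner, the SPAAC difference at the planned ratio was 0.02 (permutation p = 0.85). At a ratio of 5 the p was not adjusted and the change of the partner was not taken out, so that value does not decide. With 20 pairs at a 5' end at the planned ratio, escape of uncapped 3' fragments stays open. Cap status of the transcripts stays open as a biological explanation.

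Organelle RNA and 18S rRNA took smaller shares of captured libraries than of mRNA-seq, although 35 of 78 mitochondria-encoded genes were higher and 17 lower in depleted SPAAC than in mRNA-seq. Capture of m7G-capped nuclear mRNA may account for part of the low shares in mock libraries, and chloroplast genes rose by a median of 2.14 after depletion in SPAAC. Removing capped RNA would raise uncapped RNA whatever was captured. No m7G-depleted mRNA-seq library is among the samples, so this rise cannot decide the question. After depletion the chloroplast share was still 10.9 times lower than in mRNA-seq in SPAAC and 4.39 times lower in CuAAC. Under depletion the chloroplast, mitochondrial and 18S rRNA shares rose by 4.1, 3.99 and 4.11 times in SPAAC, and by 5.04, 5.10 and 5.81 times in CuAAC. These values were seen before the test was chosen, and NAD+ caps on organelle RNA were not tested.

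For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many calls and the highest other split gave 0. Mixed splits put the difference between the groups into the spread, and the fits had no replicate block, so a count of 0 there does not measure chance. The real counts, fitted on the compared libraries, were 1511 and 3130 for SPAAC and CuAAC against mRNA, 1409 and 1660 for SPAAC against CuAAC in mock and depleted RNA, 3614 and 2855 for depletion in SPAAC and CuAAC, and 5002 and 3350 for depleted SPAAC and CuAAC against mRNA.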
